A study of Mus musculus with 222 samples.

How the data were processed

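Single-cell RNA was measured by MARS-seq, which sorts single cells into 384-well plates and counts the 3' ends of their poly(A) RNA with molecular identifiers (UMIs), in mouse gastrulation embryos. Per the labels' protocols, embryonic stem cells lacking Tet1, Tet2 and Tet3 (TKO), pairs of them (DKO12, DKO13 and DKO23) or none (control) were injected into B6D2F1 blastocysts. Tetraploid hosts gave whole embryos made of the injected cells, and diploid hosts gave chimeras in which injected and host cells share an embryo. A further group was made by treating zygotes with floxed Tet genes with AAV1-Cre. DNA methylation was measured by PBAT bisulfite sequencing in TKO and control cells sorted from E8.5 mixed chimeras.

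The deposited plate files hold raw UMI counts per gene and well, and the labels name mm9, bcl2fastq 2.15.0.4 and Bowtie2 without saying which step each served. The submitters' processing notes state neither the gene annotation used nor how UMIs were collapsed. The deposited cell table gives, per the file headers, each well's plate, embryo, cell genotype, clone and well coordinate as names, and the sorter's GFP and tdTomato fluorescence as an intensity (a pulse area on a linear scale). How the authors called genotypes is not stated. The deposited methylation files list methylated and total read counts per CpG position of mm9, per the file headers, with no filter on coverage stated.

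The plates held 83328 wells on 217 plates, 27308 gene rows and 92 rows of spike-in RNA. Only wells to which the cell table gave a clear genotype were kept: 54314 cells from 128 embryos, with 2041 to 15427 UMIs (median 4627). A further 6203 wells had an unclear genotype, 22807 carried no annotation (3213 of those not listed as empty held about as many UMIs as kept cells) and 9 were listed more than once, and these were left out. The 4270 wells listed as empty had a median of 37 UMIs and a mean of 1250.54, so some held far more. One plate without annotated cells was not used. No doublet caller was run, since cells were sorted singly into wells, per the labels' protocols. No pair of kept cells held identical counts (0 pairs). Row names were used as deposited, and 18989 of them matched a current mouse symbol, 1844 an older one and 6114 none. Rows that join a gene with its near-identical copy, such as Rpl34;Rpl34-ps1, cannot be split.

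The files gave no cell types. Counts were scaled to 5000 per cell, log-transformed and reduced to 40 principal components of up to 1000 variable genes in the host and control cells, with cell-cycle, sex-linked, Tet, imprinted and stress genes left out. A graph of 20 neighbours of the host and control cells was clustered with leidenalg 0.10.2 (resolution 2) and igraph 0.11.9, and each cell of any genotype took the majority cluster of its 15 nearest host or control cells. Of 42 clusters, 36 were named with 20 classes from markers listed before the data were examined. A name needed at least 3 raised markers of the class, a median log2 fold over 0.5 across its markers, and no class with more markers among the 10 leading genes. The names are therefore rebuilt and can differ from the authors' own, and a difference from the study can come from that. Epiblast joined clusters 0 and 12, and 99.1% of the epiblast cells of TKO whole embryos lay in cluster 0 against 57.9% of those of control whole embryos.

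The embryo was the unit of replication. Counts of the cells of each embryo, genotype and class were summed wherever there were at least 20 cells, giving 856 sums. Each comparison was fitted per class with edgeR 4.0.16 (TMM factors, its default expression filter, quasi-likelihood F test, Benjamini-Hochberg adjustment), and a gene was called at an adjusted p under 0.05. Within chimeras the embryo was a block, since host and injected cells of one embryo are paired by the animal. The standard error of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. Adjusted p values of genes in the text come from this test. Levels are CPM of the sum, as mean ± SD over embryos. The 26 gene lists, fixed before the data were examined, were tested with limma 3.58.1 camera (preset correlation 0.01, and again with an estimated correlation), with Benjamini-Hochberg adjustment over lists. Counts adjusted over the list alone repeat the adjustment over the list's measured genes.

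Shares of cell types are the percent of an embryo's cells of one genotype, with extraembryonic types that hosts contribute left out of the denominator and types with means under 0.5% on both sides not tested. They were compared by two-sided permutation of embryos (whole embryos) or by flipping signs within embryos (chimeras), exactly or with 100000 resamples, and adjusted over types by Benjamini-Hochberg. Methylated and total calls were summed over 1000 bp windows with at least 3 CpG positions and at least 10 calls in each library. A quasi-binomial model with dispersion moderated by limma was then fitted per window, and a window was called at an adjusted p under 0.05 and a difference of at least 10 percentage points. Annotation of mm9 was not used here, so windows are given by position and not by gene.

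The genes named were set by a rule written before the data were examined. It took the Tet genes always, then the 6 highest and 6 lowest log2 fold changes among called genes with a mean of at least 20 CPM and the same direction in at least 80% of embryos, and then up to 3 called members per list with the smallest p. For windows it took the 5 largest gains and 5 largest losses with at least 30 calls in each library. A gene picked in a comparison could also be named in others without a mark. Genes outside the rule are marked where they are named.

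Alternatives were DESeq2 1.42.0, no expression filter, at least 50 cells, scaling without 883 sex-linked and mitochondrial rows, no block, leaving out each clone or, with at most 5 embryos, each embryo, and embryos of shared processing dates. For windows they were at least 20 calls, 500 bp, a difference of 20 points, limma on log ratios and a block by clone number. The planned fits of the main cell types were tested on simulated counts with 200 genes changed by known folds, and every fit was repeated on up to 100 other splits of the embryos. In whole-embryo epiblast 95.3% of simulated changes of 2-fold were found with 6.6% false calls, in chimera TKO against host epiblast 84.5% with 1.8%, and in TKO against injected control epiblast 66.3% with 7.2%. In simulated windows 32.0% of differences of 30 points were found, and 59.8% where every library had at least 30 calls. Other tools were Python 3.11.15, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and R 4.3.3.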

Results

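Single-cell UMI counts were measured in E7.5 to E8.5 mouse embryos on 217 plates, and CpG methylation in 4 libraries. Whole embryos made of injected stem cells came on 44 plates of TKO embryos (cells lacking Tet1, Tet2 and Tet3), 14 of control embryos and 4 with both. Chimeras of host and injected cells came on 45 plates with TKO cells, 49 with TKO and control cells, 25 with cells lacking Tet1 and Tet2 (DKO12), 13 with cells lacking Tet1 and Tet3 (DKO13) and 13 with cells lacking Tet2 and Tet3 (DKO23). Embryos from zygotes treated with AAV-Cre came on 10 plates. Totals per plate ran from 745912 to 3668565 UMIs in chimeras with TKO and control cells and from 1062721 to 2592147 in TKO whole embryos. Kept cells had medians of 4328 UMIs in TKO and 4660.5 in control whole embryos (10173 and 4356 cells from 30 and 13 embryos), and of 4459 in TKO, 5078 in control and 4631 in host cells of the chimeras (8357, 7251 and 7323 cells).

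The Tet genes encode dioxygenases that oxidise 5-methylcytosine, and their RNA was read first in every embryo with enough embryonic cells. Tet1 averaged 40.0 ± 17.6 CPM in TKO whole embryos (SD, n = 29, range 19.05 to 101.3) against 79.7 ± 19.3 in control whole embryos (n = 13, range 46.0 to 118). In chimeras it averaged 39.0 ± 20.0 in TKO cells (n = 40), 78.4 ± 23.8 in control cells (n = 20) and 73.8 ± 33.0 in host cells (n = 27). Tet2 averaged 1.22 CPM in TKO and 3.58 in control whole embryos, and Tet3 10.8 and 21.5. DKO13 cells had 30.5 ± 10.8 CPM of Tet1 (n = 7), DKO12 cells 47.5 ± 13.7 (n = 12) and DKO23 cells 63.1 ± 12.7 (n = 6), with hosts of 57.3, 53.7 and 57.0. Embryos treated with AAV-Cre had 66.4 ± 9.07 CPM of Tet1 (n = 7), 6.31 of Tet2 and 32.6 of Tet3. The assay counts 3' ends, and the labels do not place the deletions, so RNA that remains neither checks nor contradicts a genotype.

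Whole embryos ask what loss of Tet does when the entire embryo proper carries it. TKO embryos held almost no cells of the mesoderm that forms somites and head. Paraxial mesoderm made up 0.0461% ± 0.156 of TKO cells (n = 30) against 4.48% ± 5.19 of control cells (n = 13), and rostral and cranial mesoderm 0.0682% ± 0.218 against 1.80% ± 2.46. Lateral and intermediate mesoderm (0.145% against 1.80%), node and notochord (0.269% against 1.12%) and forebrain or rostral neural plate (0.0304% against 1.41%) were lower as well. Epiblast, the pluripotent layer from which the germ layers arise, averaged 41.4% ± 27.3 against 29.2% ± 14.6, and primitive streak, where mesoderm forms, 12.8% ± 7.16 against 8.74% ± 7.22. Haematoendothelial cells, the source of blood and vessels, averaged 4.03% ± 5.17 against 2.78% ± 1.84.

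By a two-sided permutation test over embryos, adjusted over 14 types, the difference held for paraxial mesoderm (adjusted p = 0.00112, below the control mean in 30 of 30 TKO embryos), lateral and intermediate mesoderm (0.00602), rostral and cranial mesoderm (0.00681), node and notochord (0.00973) and forebrain (0.0306). It did not hold for caudal epiblast (2.25% against 4.96%, adjusted p = 0.0708), epiblast (0.199), primitive streak (0.196) or haematoendothelial cells (0.441). The labels date TKO plates to E7.5 to E8.5 and control plates to E7.5. Among the 9 TKO and 11 control embryos processed on shared dates, permuted within date (plain means given here, the test weighting differences within date), epiblast (61.5% against 29.0%, adjusted p = 0.00574) and definitive endoderm (3.38% against 5.72%, 0.0455) differed, and paraxial mesoderm (0% against 3.72%) had an adjusted p = 0.13. Lateral and intermediate mesoderm, rostral and cranial mesoderm, node and notochord, and forebrain were not called there either. Haematoendothelial cells there averaged 0.616% against 2.71% (p = 0.0144, adjusted p = 0.0670).

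**Figure D1:**
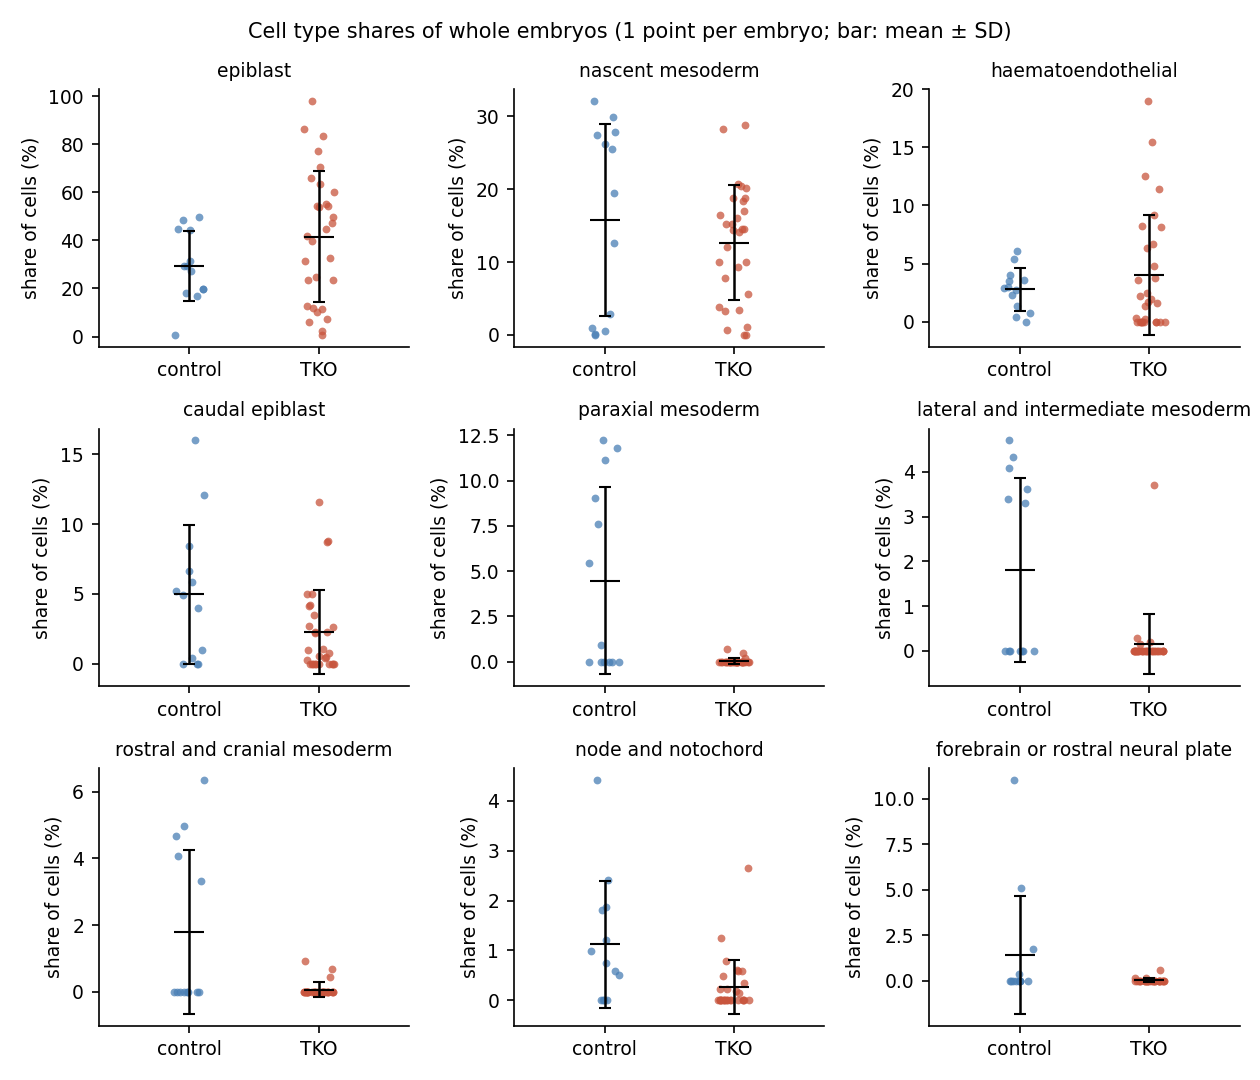
Percent of each whole embryo's embryonic cells in each cell type, for 30 TKO and 13 control embryos; points are embryos and bars are mean and SD. Paraxial mesoderm averaged 0.0461% in TKO and 4.48% in control embryos.

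In the epiblast of whole embryos, some genes of the Nodal pathway, which patterns the early embryo, were higher in TKO than in control embryos. Nodal itself rose 3.17-fold (log2 1.66 ± 0.25 SE, 64.1 ± 25.4 against 20.0 ± 14.8 CPM, 27 of 27 TKO embryos above the control mean of 12). Its relative Gdf3 rose 4.27-fold (2.09 ± 0.35) and the inhibitor Smad7 2.63-fold (1.39 ± 0.31). The inhibitors of differentiation Id2 and Id3, which respond to BMP, fell by 1.99 ± 0.25 and 0.94 ± 0.11 on the log2 scale. T (brachyury, a streak regulator, −2.02 ± 0.37), Sp8 (−1.90 ± 0.31) and the Wnt feedback genes Nkd1 (2.82-fold) and Axin2 (−0.71 ± 0.18) fell as well, but this followed which epiblast cells each genotype held. With cluster 0 cells alone T was higher (0.99), Sp8 (−0.25), Nkd1 (−0.10) and Axin2 (−0.02) were not called, and Nodal (1.10), Id2 (−1.43) and Id3 (−0.95) were. Tet1 was lower by 1.09 ± 0.13 (edgeR quasi-likelihood, BH-adjusted p = 1.48e-08).

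Of 8 measured Nodal and Lefty genes, 5 rose and none fell (5 and 0 adjusted over the list alone; camera adjusted p = 0.000309, and adjusted p = 0.0570 with an estimated correlation). Of 8 Wnt genes 0 rose and 4 fell (0 and 4 adjusted over the list alone), and of 6 BMP genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), with camera adjusted p = 0.207 and 0.122. The list counts in this paragraph use epiblast cells of both clusters. With cluster 0 cells alone the Wnt feedback genes Nkd1 and Axin2 were not called, as given above. Of 17 pluripotency genes 7 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.119). Dppa4 rose 16.9-fold (4.08 ± 0.66), Pou5f1 2.19-fold and Fgf4 2.71-fold, and Sox2 (−0.94 ± 0.16) fell. Imprinted genes, read from 1 parental copy, went both ways: 2 of 20 rose and 6 fell (2 and 7 adjusted over the list alone), with H19 at 2.23 ± 0.44 and Grb10 at −1.44 ± 0.28. Of 6 basement membrane genes shared with parietal endoderm 3 were higher (among them Sparc 1.25 ± 0.15 and Col4a1 1.15 ± 0.14) and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.122). Ccng1, a p53 target, rose 1.89-fold (0.92 ± 0.20), and averaged 193 and 207 CPM in chimera cells of clones TKO26 and TKO29 but 79.8 in those of clone TKO23.

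Across the epiblast 1068 genes were higher and 1106 lower of 7424 tested (27 TKO and 12 control embryos, edgeR), and 2991 had an unadjusted p under 0.05. The lowest were Hspa8, a chaperone (43.1-fold, 13.6 ± 10.9 against 602 ± 121 CPM), Mid1 (38.0-fold), Rpl34;Rpl34-ps1 (26.6-fold) and Tpm3 (18.3-fold), and the highest AK207688 (19.7-fold). Hspa8 averaged 36.7 and 39.8 CPM in the chimera cells of clones TKO26 and TKO29, which made the whole embryos, and 561 ± 101 in those of clone TKO23. Of 2039 other called genes measured there, 1706 (83.7%) changed in the same direction in TKO23 epiblast against injected control cells of other embryos. The slope on the whole-embryo effects over all called genes measured was 0.513 in TKO23 and 0.871 in TKO26 and TKO29. On shared dates 1104 genes were called, and 1088 with date as a term. With only the cells of cluster 0, which held 99.1% of TKO and 57.9% of control epiblast cells, 1512 were called.

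**Figure D2:**
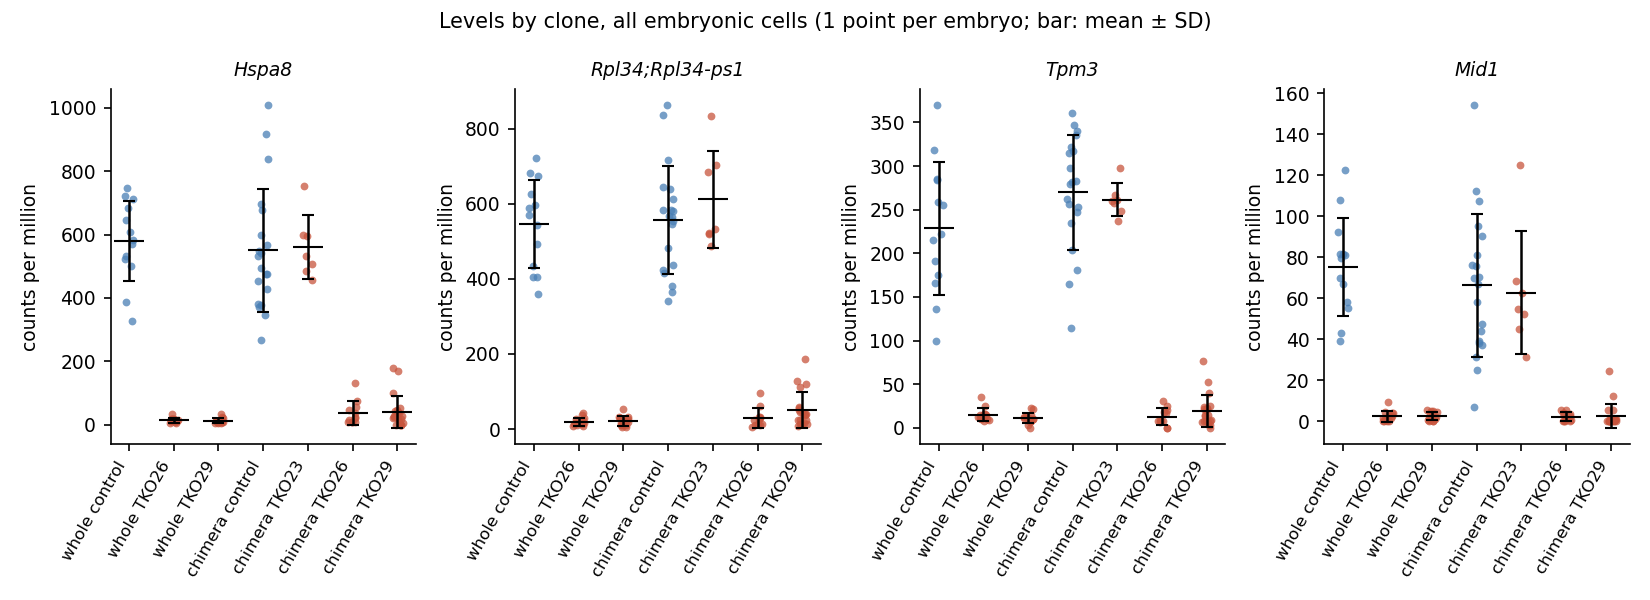
Levels (CPM) of Hspa8, Rpl34;Rpl34-ps1, Tpm3 and Mid1 in all embryonic cells, by group and stem cell clone; each point is an embryo, with the mean and SD as bars. Hspa8 averaged 13.5 CPM in TKO whole embryos and 580 in control whole embryos, and 561 in chimera cells of clone TKO23.

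In nascent mesoderm, the cells that have just left the streak, genes moved both ways in TKO whole embryos. Mixl1 stood at 1474 ± 374 against 614 ± 376 CPM (1.24 ± 0.23, n = 20 and 8), Gsc rose 2.61-fold and Wnt3 1.92-fold, and 5 of 13 streak genes rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0764). The Notch ligands Dll1 (−1.66 ± 0.28) and Jag1 (−1.76 ± 0.20), the FGF feedback gene Spry2 (−1.18 ± 0.18), Fgf15 (−1.56 ± 0.21), Lefty2 (−1.41 ± 0.30) and the paraxial regulators Foxc1 (−0.86 ± 0.31) and Foxc2 (−1.46 ± 0.52) fell. Of 10 Notch genes 1 rose and 3 fell (1 and 3 adjusted over the list alone), and of 11 FGF genes 1 rose and 4 fell (3 and 6 adjusted over the list alone). Fgf10 rose 2.11-fold and Etv2, which starts the blood and vessel programme, 2.71-fold (edgeR, BH-adjusted p = 0.00155). Imprinted genes moved both ways, 2 of 19 higher and 7 lower (3 and 9 adjusted over the list alone). In all, 562 genes were higher and 501 lower of 6059 tested. On shared dates 423 were called, and 263 with date as a term.

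Extraembryonic mesoderm of whole embryos forms allantois and yolk sac mesoderm. Its H19, a maternally expressed RNA, stood at 6274 ± 2700 CPM in TKO (n = 12) and 31.6 ± 16.7 in control embryos (n = 7), 186-fold apart (7.54 ± 0.40). In chimeras it averaged 1306 and 1174 CPM over all embryonic cells of clones TKO26 and TKO29, 128 in clone TKO23, 95.3 in injected control and 2060 in host cells. Of 24 imprinted genes 8 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.302), including Rian (2.80 ± 0.63, in the row AF357425;Rian) and Peg3 (1.35 ± 0.27). Of 12 p53 targets 6 rose and none fell (7 and 0 adjusted over the list alone), with Ccng1 at 2.60-fold, Perp at 2.52-fold and Phlda3 at 2.35-fold. That list's camera adjusted p = 0.00678 (adjusted p = 0.311 with an estimated correlation). Trophoblast genes (4 of 6 higher, 5 adjusted over the list alone, among them Plac1 0.78 ± 0.18 and Peg10 0.60 ± 0.15) had camera adjusted p = 0.0165 (adjusted p = 0.0759 with an estimated correlation). Of 10 stress genes 2 were higher and 3 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.000488, and 0.00823 with an estimated correlation), with a median log2 change of −0.25 and a mean of −0.63, and with Hspa8 at −5.62 ± 0.21 and Hsp90aa1 at −1.03 ± 0.26. Plac8 fell 6.22-fold (−2.64 ± 0.26), Gdf6 5.56-fold and the cardiac light chain Myl7 4.00-fold. The embryonic globins Hba-x (45.7-fold) and Hbb-bh1 (13.7-fold) were higher, in 8 of 12 TKO embryos each. Asb4 fell (−1.04 ± 0.37), and Acta2 (1.16 ± 0.62), Tagln (−0.10 ± 0.39) and Col1a1 (0.24 ± 0.32) were not called. In all, 841 genes were higher and 881 lower of 7540 tested. The labels date TKO plates to E7.5 to E8.5 and control plates to E7.5, and no fit on shared dates is given for this type. Stage and genotype therefore cannot be told apart for these changes, the globins among them.

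The other cell types of whole embryos gave fewer calls. Caudal epiblast had 202 genes higher and 172 lower (6 TKO and 5 control embryos), primitive streak 272 and 244 (24 and 5), erythroid cells 150 and 122 (5 and 4) and definitive endoderm 66 and 92 (10 and 5).

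Chimeras ask what TKO cells do beside wild-type cells of the same embryo. TKO cells gave fewer blood, endoderm and forebrain cells than both the host cells and the injected control cells of their embryos. They gave more caudal epiblast, but with clusters made without the called genes its difference from control cells fell to 1.59 points (adjusted p = 0.146) and that from host cells to 1.95 (adjusted p = 0.01225). With at least 50 cells the fall of erythroid cells against control cells (−2.23 points, adjusted p = 0.0531, n = 13) was not called. Haematoendothelial cells made up 0.647% ± 1.31 of TKO and 5.86% ± 2.80 of injected control cells (lower in 19 of 19 embryos), and 1.59% ± 2.10 of TKO and 3.75% ± 2.82 of host cells (lower in 23 of 30). Erythroid cells averaged 0% of TKO against 2.35% of control cells, and 0.539% against 9.24% of host cells. Definitive endoderm averaged 1.66% against 5.42% of control and 3.02% against 10.7% of host cells. Caudal epiblast, which feeds the trunk, averaged 17.1% ± 12.2 against 9.13% ± 8.22 of control cells and 15.8% ± 11.3 against 9.63% ± 8.92 of host cells. Paraxial mesoderm averaged 5.04% of TKO and 3.66% of control cells.

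These shares were tested by flipping signs within embryos (two-sided permutation, adjusted over 17 types). Against control cells (n = 19) the adjusted p was 0.00051 for haematoendothelial cells, 0.00085 for endoderm, 0.00136 for caudal epiblast, 0.00677 for erythroid cells and forebrain, 0.0116 for streak (11.7% against 4.65%), 0.0390 for node and notochord and 0.04998 for paraxial mesoderm. With at least 50 cells (n = 13) streak (1.68 points, down from 7.10), node (−0.587) and paraxial mesoderm (1.84) were not called, and new clusters left paraxial mesoderm at 0.649, not called either. Against host cells (n = 30) it was 8.5e-05 for endoderm and erythroid cells, whose p of 1e-05 is the smallest the resamples can give, 0.000283 for caudal epiblast and 0.00231 for haematoendothelial cells. It was 0.000382 for extraembryonic mesoderm (19.5% against 8.66%), 0.0104 for forebrain, 0.0141 for node, 0.0166 for cardiac mesoderm and 0.0337 for streak. Cardiac mesoderm with new clusters (−0.758 points) and streak with at least 50 cells (2.66) were not called. Injected control cells against host cells (n = 13, exact) gave no adjusted p under 0.266. Hosts also supply the extraembryonic endoderm and trophoblast, which were left out of all shares.

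**Figure D3:**
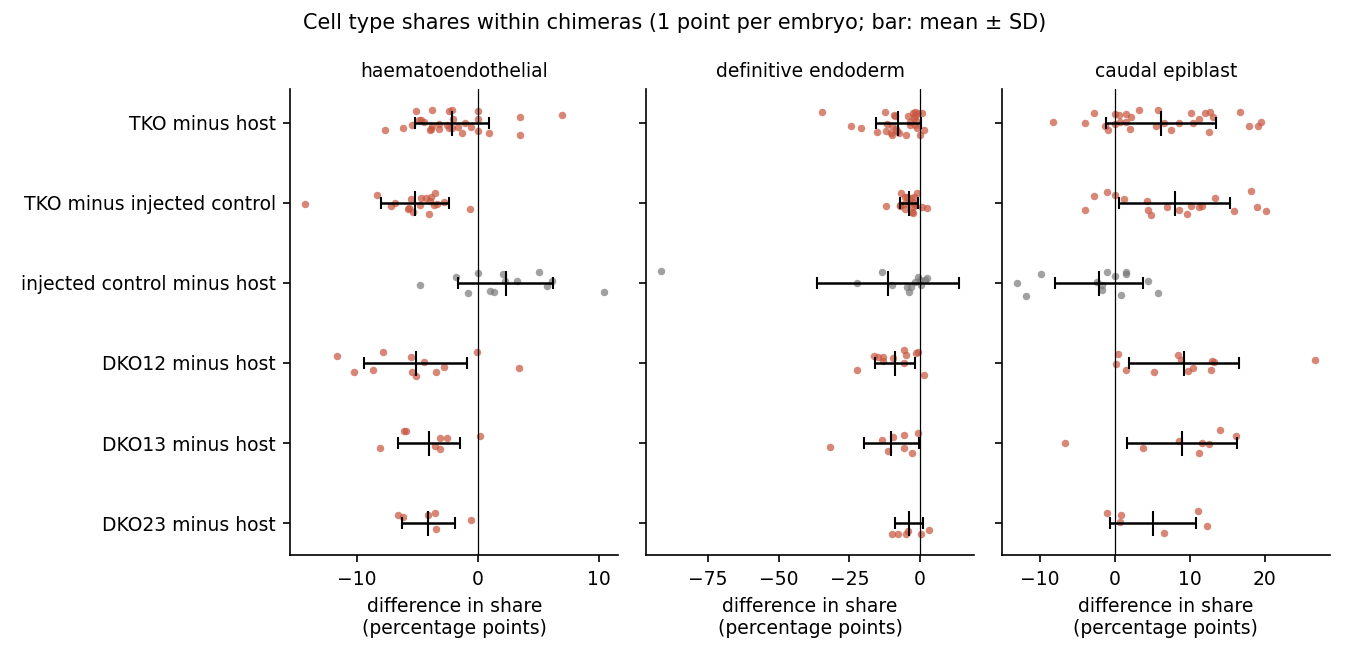
Difference in the percent of haematoendothelial, definitive endoderm and caudal epiblast cells within chimeric embryos (percentage points, injected minus host or TKO minus injected control), with 1 point per embryo and mean and SD as bars. TKO cells lay 5.21 points below injected control cells in haematoendothelial cells and 8.00 points above them in caudal epiblast (1.59 with clusters made without the called genes).

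TKO caudal epiblast was compared with host cells of the same embryos. Cdx1, a posterior homeobox regulator, fell 2.60-fold (386 ± 176 against 989 ± 528 CPM, log2 −1.38 ± 0.11, 9 of 9 embryos), Wnt8a 2.39-fold and Aldh1a2, which makes retinoic acid, 2.97-fold. Mixl1 (0.95 ± 0.18) and Hand1 (0.73 ± 0.14) rose. Neural genes fell in 2 of 6 (Sox3 −0.71 ± 0.18, Crabp2 −0.44 ± 0.14; 2 adjusted over the list alone; camera adjusted p = 0.0354, and adjusted p = 0.275 with an estimated correlation). Of 16 imprinted genes 2 rose and 5 fell (3 and 6 adjusted over the list alone), led by Grb10 (−2.19 ± 0.20) and Nnat (−2.03 ± 0.24), and of 4 parietal endoderm genes 3 rose (3 adjusted over the list alone; Sparc 0.91 ± 0.15, Lamb1 0.79 ± 0.16, Col4a1 0.62 ± 0.19). Camera's adjusted p was 0.000293 and 0.000608 for these lists, and each had an adjusted p = 0.0359 with an estimated correlation. Ccng1 rose 3.29-fold (1.72 ± 0.18). In all, 222 genes were higher and 156 lower of 3936 (edgeR with embryo as a block); without clone TKO26 91 were called, against 378 with all clones.

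In the epiblast (7 embryos) Tet1 was lower by 0.93 ± 0.19 (edgeR, BH-adjusted p = 0.000702), and 272 genes were higher and 205 lower of 4695. The streak regulator Eomes (0.49 ± 0.14), the Nodal co-receptor Tdgf1 (0.71 ± 0.15) and Col4a1 (1.11 ± 0.23) rose, and Utf1, a pluripotency factor, fell (−0.73 ± 0.09, 601 ± 103 against 1012 ± 155 CPM). The methyltransferases Dnmt3a (−0.33 ± 0.09) and Dnmt3b (−0.23 ± 0.06) fell slightly. Of 10 imprinted genes 5 fell (6 adjusted over the list alone), among them Peg3 (−1.19 ± 0.24) and Grb10 (−1.49 ± 0.14), with camera adjusted p = 1.11e-05 (adjusted p = 0.107 with an estimated correlation). Of 3 visceral endoderm genes 2 fell (2 adjusted over the list alone; camera adjusted p = 0.00919, and adjusted p = 0.166 with an estimated correlation), and of 4 parietal endoderm genes 2 rose (3; 0.00749, and adjusted p = 0.135 with an estimated correlation). Tnfrsf1a rose 8.72-fold and Crip2 fell 2.98-fold. Without clone TKO29 198 genes were called, against 477 with all clones.

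In extraembryonic mesoderm (7 embryos) the contractile genes Acta2 (−2.13 ± 0.30, 141 ± 211 against 497 ± 386 CPM) and Tagln (−2.29 ± 0.35) fell, and so did Plac8 (−3.00 ± 0.30), Col1a1 (−2.24 ± 0.29), Dlk1 (−1.08 ± 0.27) and the imprinted Asb4 (−3.19 ± 0.27). Of 20 imprinted genes none rose and 6 fell (2 and 11 adjusted over the list alone; camera adjusted p = 1.19e-09, and adjusted p = 0.0823 with an estimated correlation). Of 6 cardiac genes 2 fell (2 adjusted over the list alone), with camera adjusted p = 0.0013 and adjusted p = 0.159 with an estimated correlation. Ifitm1 (0.89 ± 0.15) and Id2 (0.77 ± 0.15) rose. In all, 119 genes were higher and 103 lower of 4694; without clone TKO26 39 were called. Forebrain (113 and 88, n = 3), paraxial mesoderm (36 and 29, n = 4) and nascent mesoderm (2 and 8, n = 3) gave smaller sets.

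Per the labels' protocols control cells were cultured and injected as TKO cells were, but differences between stem cell lines remain in this comparison. In caudal epiblast (6 embryos) the neural genes Sox2 and Sox3 were lower in TKO cells, Sox2 2.97-fold (35.7 ± 17.6 against 107 ± 44.0 CPM, −1.57 ± 0.24) and Sox3 2.77-fold (−1.47 ± 0.23). So were Hoxa3 (−1.43 ± 0.28) and Hoxb9 (−1.41 ± 0.20), the FGF feedback genes Spry2 (−1.11 ± 0.16) and Etv4 (−0.96 ± 0.22), Hes3 (−1.42 ± 0.32) and Dll1 (−0.97 ± 0.26) of the Notch pathway and Cdx1 (−0.80 ± 0.12). The mesoderm genes Mixl1 (1.01 ± 0.24), Mesp1 (0.89 ± 0.25), Twist1 (0.93 ± 0.21) and Hand1 (0.62 ± 0.15) were higher. No list of these genes kept its call with an estimated correlation (adjusted p = 0.161 to 0.282). By list, 3 of 8 neural genes fell (4 adjusted over the list alone), 4 of 12 Hox genes (6 lower, 1 higher adjusted over the list alone), 3 of 12 FGF genes with 1 higher (5 lower, 1 higher) and 2 of 11 Notch genes (3 lower, 1 higher). Of 10 paraxial genes 3 rose (4 higher, 1 lower adjusted over the list alone) and of 11 lateral genes 5 (5 higher). Their camera adjusted p ran from 0.00121 for neural genes to 0.0251 for Notch genes. In all, 130 genes were higher and 125 lower of 5598.

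In the epiblast only 3 embryos had enough cells of both kinds. Over all chimeras with TKO or control cells cluster 0 held 94.8% of TKO and 73.9% of control epiblast cells. With cluster 0 cells alone 119 genes were called, 118 of them also called with all epiblast cells, T (2.04) and Tet1 (−1.28) among them, while Id2 was not called. Tet1 was 2.30-fold lower (−1.20 ± 0.27), T rose 4.29-fold (58.1 ± 13.8 against 14.5 ± 10.2 CPM), Tdgf1 1.90-fold and Dppa4 22.3-fold, and Id2 (−1.02 ± 0.28), Id3 (−0.79 ± 0.18) and Sox2 fell. The imprinted Impact (−4.65 ± 0.58), Nnat (−2.53 ± 0.48) and Grb10 (−1.29 ± 0.22) fell among 5 of 13 (1 higher and 5 lower adjusted over the list alone; camera adjusted p = 4.63e-05, and adjusted p = 0.856 with an estimated correlation). Mid1, Tpm3, Hspa8 and Rpl34;Rpl34-ps1 were again among the lowest, by 13.8- to 49.6-fold. Of 5646 genes 80 were higher and 49 lower, and leaving out embryo TKO26_2, TKO26_7 or TKO29_8 gave 13, 72 or 209.

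In extraembryonic mesoderm (7 embryos) the contractile genes Actc1 (−2.13 ± 0.32), Tagln (−1.52 ± 0.35) and Acta2 (−1.12 ± 0.30) fell also against control cells. The matrix gene Postn (−1.24 ± 0.25), Dlk1 (−1.29 ± 0.23), Col1a1 (−1.94 ± 0.19), Plac8 (−2.75 ± 0.30) and Asb4 (−2.13 ± 0.20) fell, and Cdx2 (0.76 ± 0.17), Ifitm1 (1.06 ± 0.17) and Id2 (0.67 ± 0.14) rose. Of 9 cardiac genes 3 fell (6 adjusted over the list alone; camera adjusted p = 0.00227, and adjusted p = 0.215 with an estimated correlation). Of 21 imprinted genes 1 rose and 10 fell (2 and 11 adjusted over the list alone; camera adjusted p = 5.58e-12, and adjusted p = 0.0551 with an estimated correlation). Tet3 was 2.67-fold lower (edgeR, BH-adjusted p = 0.00218). In all, 152 genes were higher and 169 lower of 5535.

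Injected control cells were called different from host cells in fewer genes than TKO cells were in extraembryonic mesoderm and caudal epiblast, led by imprinted ones. These fits had fewer embryos than those of TKO cells, so the counts do not compare like with like. In extraembryonic mesoderm (5 embryos) H19 was 34.1-fold lower (239 ± 201 against 7735 ± 2333 CPM, −5.09 ± 0.24) and the growth factor Igf2, which lies beside it, 2.00-fold higher (1.00 ± 0.08). Slc38a4 (0.68 ± 0.12) and Zdbf2 (1.14 ± 0.24) were higher and Pfn1 (−1.47 ± 0.17) and Ifitm1 (−0.83 ± 0.17) lower, among 7 higher and 9 lower genes of 4705 and 3 higher and 1 lower of 22 imprinted genes (3 and 3 adjusted over the list alone). Rostral and cranial mesoderm (4 embryos) gave 8 higher and 8 lower of 5113, with H19 at −4.25 ± 0.31, Igf2 at 0.73 ± 0.11, Mest at −0.80 ± 0.12 and the somite gene Meox1 at −0.88 ± 0.17. Caudal epiblast (3 embryos) gave 13 and 9. Counts moved with single embryos: in extraembryonic mesoderm leaving out TKO29_2, TKO26_8 or TKO29_16 gave 5, 9 or 25.

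Double knockouts ask which Tet genes matter. In DKO12 caudal epiblast, mesoderm genes were higher than in host cells (5 embryos). A different mix of cells within this class was not checked. Over all embryos 52 DKO12 cells and 1 host cell were named nascent mesoderm, and 46 and 4 primitive streak. Bmp4 rose 4.81-fold (164 ± 109 against 36.7 ± 30.0 CPM, 2.27 ± 0.28), Mixl1 3.68-fold (1.88 ± 0.25), Msx1 3.13-fold, Hand1 2.96-fold and Mesp1 2.81-fold. Of neural and pluripotency genes Sox3 fell 2.94-fold (−1.56 ± 0.17), Ptn 4.25-fold and Pim2 3.96-fold, as did Dnmt3b (−1.12 ± 0.12). Of 11 lateral mesoderm genes 10 rose (11 adjusted over the list alone), of 7 paraxial genes 6 (7), of 8 BMP genes 5 (5), and of 12 streak genes 7 rose and 1 fell (8 and 2). Of 7 neural genes 3 fell (1 higher and 4 lower adjusted over the list alone), of 6 pluripotency genes 2 (4) and of 5 methylation genes 2 (3). Camera's adjusted p ran from 1.66e-26 for lateral mesoderm to 5.08e-05 for methylation genes, and all of these stayed between adjusted p = 0.0362 and 0.0463 with an estimated correlation. Imprinted genes rose in 6 of 17 and fell in 1 (9 and 4 adjusted over the list alone), with Phlda2 at 2.05 ± 0.15 and Slc38a4 at 1.56 ± 0.17 (camera adjusted p = 1.63e-08, and adjusted p = 0.0524 with an estimated correlation). In all, 133 genes were higher and 70 lower of 4683, and without embryo DKO12_4 or DKO12_5 82 or 83 were called.

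In DKO12 extraembryonic mesoderm (8 embryos) 6 of 10 cardiac and contractile genes fell (1 higher and 6 lower adjusted over the list alone), with Acta2 at −1.61 ± 0.30, Tagln at −1.81 ± 0.25 and Myl7 at −1.10 ± 0.24. That list's camera adjusted p = 3.84e-07 (adjusted p = 0.0988 with an estimated correlation). The collagen gene Col1a1 (−2.09 ± 0.22), Plac8 (−1.95 ± 0.26), Asb4 (−2.25 ± 0.24) and Magohb (−3.47 ± 0.30) fell in 8 of 8 embryos, and the chemokine receptor Cxcr4 (1.39 ± 0.22), Ccng1 (1.17 ± 0.17) and Phlda2 (0.81 ± 0.09) rose in 8 of 8. In all, 50 genes were higher and 59 lower of 5214. With at least 50 cells per sum 2 were called. Lateral mesoderm (35 and 44), paraxial mesoderm (44 and 20) and forebrain (0 and 3) rested on 3 embryos each, and without DKO12_4 lateral mesoderm gave 0 calls.

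Shares of DKO12 cells were tested in 12 embryos (exact, within embryos). Erythroid cells averaged 0.577% of DKO12 and 12.1% of host cells (adjusted p = 0.00342, lower in 12 of 12), haematoendothelial cells 1.602% against 6.78% and definitive endoderm 3.78% against 12.6% (each 0.00684). Caudal epiblast averaged 18.0% against 8.82% (0.00342, higher in 12 of 12), paraxial mesoderm 10.5% against 6.10%, lateral mesoderm 8.17% against 5.20% (each 0.00684) and epiblast 9.37% against 4.88% (0.0391). With clusters made without the called genes the differences in paraxial mesoderm (3.05 points, adjusted p = 0.104) and epiblast (1.45, 0.0684) were not called.

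DKO13 cells (8 embryos) gave fewer erythroid (1.88% against 12.2%), haematoendothelial (1.14% against 5.19%) and endoderm cells (3.95% against 14.0%), and more paraxial (12.0% against 4.76%) and rostral mesoderm (9.10% against 5.78%), each with an exact adjusted p = 0.0406. With at least 50 cells (7 embryos) each had an adjusted p = 0.075. Their extraembryonic mesoderm (4 embryos) had lower Plac8 (−2.51 ± 0.22, 51.7 ± 40.2 against 311 ± 105 CPM), Col1a1 (−2.12 ± 0.25), Asb4 (−1.97 ± 0.30), Acta2 (−1.65 ± 0.29) and Tagln (3.04-fold), the keratin gene Krt19 (−1.72 ± 0.25), and the signals Bmp2 (−1.13 ± 0.19) and Wnt5a (−1.20 ± 0.26). Ccng1 (1.18 ± 0.20) and Psrc1 (1.74 ± 0.33) rose. Of 7 cardiac genes 2 fell (3 adjusted over the list alone) and of 19 imprinted genes 4 (1 higher and 5 lower adjusted over the list alone), with camera adjusted p = 0.00224 and 6.91e-05 and an adjusted p = 0.290 with an estimated correlation for each. In all, 9 genes were higher and 42 lower of 4514; without DKO13_3, DKO13_4 or DKO13_5 27, 28 or 30 were called.

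DKO23 cells, which keep Tet1, differed in direction for the contractile genes. Ccng1 rose in DKO23 cells too, as in DKO12 and DKO13 cells, in extraembryonic mesoderm (1.00 ± 0.29, edgeR BH-adjusted p = 0.0426) and forebrain (0.77 ± 0.22, 0.0485). In extraembryonic mesoderm (4 embryos) Tagln (0.75 ± 0.19, 240 ± 60.0 against 155 ± 57.9 CPM, higher in 3 of 4 embryos) and Acta2 (0.55 ± 0.15, higher in 2 of 4 embryos) were higher, with Krt8 (0.62 ± 0.11) and Krt18 (0.36 ± 0.10). Cdx2 (−0.85 ± 0.23), Dlk1 (−0.47 ± 0.12) and Asb4 (−0.95 ± 0.24) were lower. Plac8 (−0.07 ± 0.17) and Col1a1 (0.25 ± 0.18) were not called. In injected control against host cells Tagln (0.78 ± 0.22), Acta2 (0.30 ± 0.16), Krt8 (0.29 ± 0.11) and Krt18 (0.13 ± 0.12) were also higher and Cdx2 (−0.47 ± 0.22) lower. None of these was called there, nor were Dlk1 (−0.07 ± 0.13) and Asb4 (0.32 ± 0.26). The rise of Tagln in DKO23 cells can therefore not be told from a difference of injected from host cells. H19 was 23.9-fold lower (−4.58 ± 0.10), the lowest gene, and Igf2 higher (0.95 ± 0.08), as both were in injected control against host cells. Of 20 imprinted genes 3 rose and 4 fell (3 and 4 adjusted over the list alone), their median log2 change 0.07 and mean −0.19 (camera adjusted p = 0.00241, and adjusted p = 0.558 with an estimated correlation). In all, 36 genes were higher and 37 lower of 4961. In forebrain (4 embryos) the neural genes Hesx1 (−1.30 ± 0.18, 134 ± 58.7 against 336 ± 130 CPM) and Six3 (−1.02 ± 0.22) and the Wnt receptor gene Fzd5 (−1.11 ± 0.20) fell, among 15 higher and 37 lower of 4199. The smallest p values there belonged to Atp5b (−1.04) and Cdk4 (−0.99), both named outside the rule, and Nap1l1 (−1.06). Baz2a (−1.57) and Krr1 (−1.03) fell there and in extraembryonic mesoderm (−1.51 and −1.52). Each double knockout came as its own line, so line and loss of Tet cannot be told apart. Of 10 neural genes 2 fell (3 adjusted over the list alone; camera adjusted p = 0.0127, and adjusted p = 0.249 with an estimated correlation). Without DKO23_2 or DKO23_5 26 or 28 genes were called there. No share differed after adjustment (6 embryos, exact, lowest adjusted p = 0.188), though erythroid (4.92% against 10.6%) and haematoendothelial cells (2.45% against 6.55%) were lower in 6 of 6 embryos, each p = 0.0312, the smallest 6 pairs allow.

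**Figure D4:**
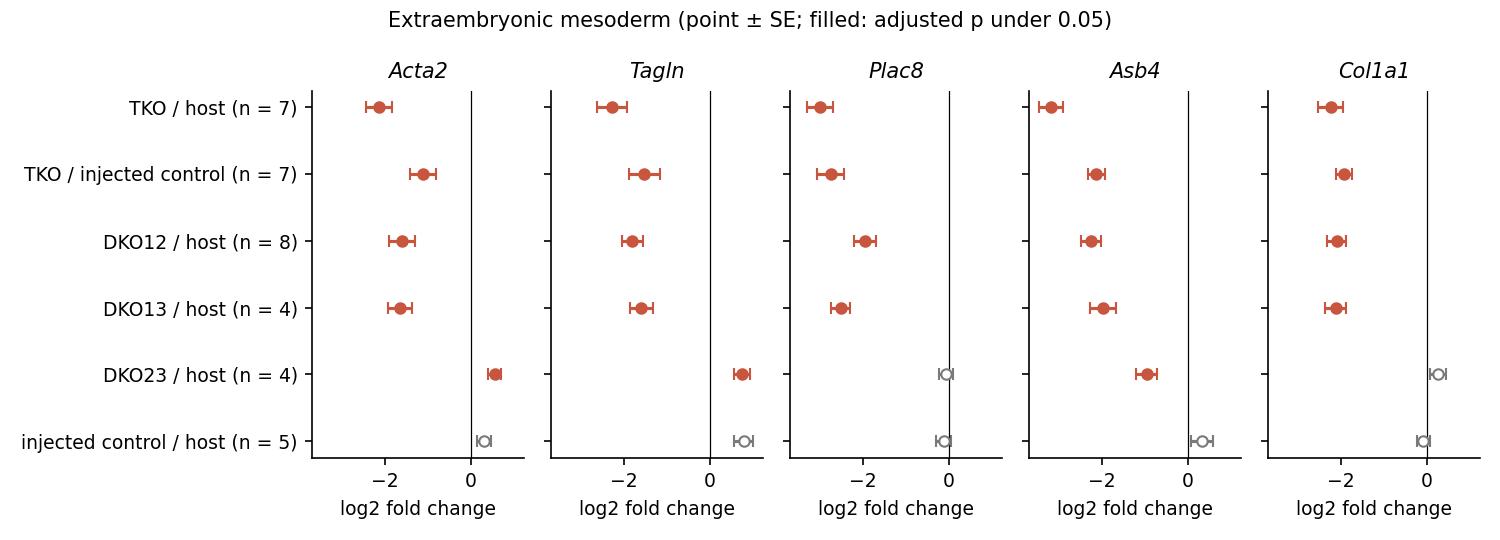
Log2 fold change (± SE) of Acta2, Tagln, Plac8, Asb4 and Col1a1 in extraembryonic mesoderm, injected minus host cells or TKO minus injected control cells; filled points had an adjusted p under 0.05. Tagln stood at −2.29 in TKO, −1.81 in DKO12 and 0.75 in DKO23 cells.

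Genes lower in extraembryonic mesoderm overlapped between sets of different embryos. Each set compares an injected line with host cells, so differences of injected from host cells can be shared whatever the Tet genotype. H19, for example, was lower in DKO13 (−4.3), DKO23 (−4.6) and injected control cells (−5.1). Overlap with genes lower in injected control cells was not tested, so these overlaps do not single out a Tet effect. Of 103 genes lower in TKO and 48 lower in DKO12 cells among 4617 tested in both, 28 were shared (1.07 for independent lists, Fisher's exact p = 1.32e-35), and with DKO13 17 of 101 and 39 (0.915, p = 1.64e-18). TKO and DKO23 shared 7 of 103 and 37 (0.845, p = 1.55e-05), DKO12 and DKO23 10 of 57 and 37 (0.437, p = 6.36e-12), and DKO13 and DKO23 16 of 41 and 35 (0.326, p = 4.16e-25). DKO12 and DKO13 shared 19 of 50 and 41 (0.458, p = 3.46e-28). Of genes higher there TKO and DKO12 shared 10 of 114 and 49 (1.21, p = 2.07e-07), and TKO and DKO23 2 of 114 and 34 (0.859, p = 0.212). Tested against each other, the DKO12 effect lay below the DKO23 effect for Tagln (−2.54, edgeR BH-adjusted p = 0.000700), Col1a1 (−2.34), Plac8 (−1.84) and Acta2 (−2.11, 0.0405), and the DKO13 effect below it for Plac8 (−2.43), Col1a1 (−2.39) and Tagln (−2.35, 0.0115). Acta2 in DKO13 (−2.19, adjusted p = 0.183) and Asb4 in DKO12 (−1.30, 0.229) and DKO13 (−1.03, 0.766) did not pass. The DKO12 effect stood apart from that of DKO23 in 25 of 6243 genes and the DKO13 effect in 7. For DKO12 3 of 50 splits called as many, so chance is not excluded for that count.

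Embryos from zygotes treated with AAV-Cre ask for the same loss without stem cells, with control whole embryos as the reference. The arms differ in stem cell origin, strain and plates as well as in the intended loss of Tet, which RNA does not check here. The control embryos are those also set against TKO whole embryos, so changes seen in both comparisons are not independent. Cluster 0 held 99.0% of AAV-Cre and 57.9% of control epiblast cells. With cluster 0 cells alone 2721 genes were called, with Nodal at 1.19, Id2 at −0.66 and Id3 at −0.79, each called. In the epiblast (7 and 12 embryos) Nodal rose 3.41-fold (74.7 ± 29.9 against 20.3 ± 15.1 CPM, 1.77 ± 0.34), Lef1, a Wnt effector, 3.50-fold, Sparc 3.00-fold and Utf1 1.95-fold, and Id2 (−1.35 ± 0.31), Id3 (−0.78 ± 0.15) and Spry2 (−0.89 ± 0.24) fell. Tet1 (−0.13 ± 0.15, edgeR BH-adjusted p = 0.530) was not called and Tet3 was higher (0.84 ± 0.21). Imprinted genes went both ways, 4 of 18 higher and 6 lower (4 and 6 adjusted over the list alone), with H19 at 2.44 ± 0.24 and Peg3 at 1.96 ± 0.29. In nascent mesoderm (7 and 8) Lefty2 fell 7.84-fold, Jag1 2.05-fold and Spry2 2.55-fold. Bmp4 rose 5.56-fold, Lhx1 4.36-fold, and the vascular receptor Kdr 2.94-fold and Etv2 2.55-fold. All 3 measured haematoendothelial genes rose (3 adjusted over the list alone; camera adjusted p = 0.0173, and adjusted p = 0.148 with an estimated correlation), and 7 of 10 lateral mesoderm genes (7; 0.00663, and adjusted p = 0.195 with an estimated correlation). Lists of other tissues rose there too, 4 of 5 neural and 4 of 5 parietal endoderm genes (4 each adjusted over the list alone; camera adjusted p = 0.0164 each, and adjusted p = 0.148 with an estimated correlation). In primitive streak (5 and 5) Rspo3 rose 4.91-fold and T 2.44-fold, and Foxa2, an endoderm regulator, fell 3.26-fold. Ccng1 fell, by 1.44 ± 0.29 in nascent mesoderm and 0.84 ± 0.29 in streak on the log2 scale. Calls were 1466 higher and 1469 lower of 6972 in epiblast, 1245 and 1239 of 5650 in nascent mesoderm and 1227 in all, 611 of them lower, of 3962 in streak.

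The TKO effect in whole embryos was set against that in chimeras by a test of the difference. In shares, haematoendothelial cells differed: TKO minus control was 5.61 points higher in whole embryos than in chimeras (two-sided permutation over 30, 13, 45 and 23 embryos, adjusted p = 0.00051). This test and the fits below take TKO and control cells of the same chimera as separate embryos, though 19 chimeras had enough cells of both. Haematoendothelial cells averaged 4.03% of TKO and 2.78% of control cells in whole embryos, and 1.35% and 5.70% in chimeras. The lower control share in whole embryos leaves less room for a fall there. On shared dates, as given above, the whole-embryo share was lower in TKO than in control embryos. Caudal epiblast (−7.84 points) and paraxial mesoderm (−4.52) had an adjusted p = 0.210 each. In epiblast expression 5 of 7632 genes differed. Hspa8 (−3.69 ± 0.55), Mid1 (−3.40 ± 0.56), Rpl34;Rpl34-ps1 (−3.08 ± 0.51) and Tpm3 (−2.58 ± 0.50) had lower effects in whole embryos, and 2310039H08Rik, named because it completes that count, a higher one (1.46). With cluster 0 cells alone 4 genes were called, all lower, and Tpm3 (−2.43) and 2310039H08Rik (1.43) were not. Clone TKO23 was in the chimeras and not in the whole embryos, and its Hspa8 was not called against injected control cells (log2 −0.15 ± 0.17 in epiblast). In extraembryonic mesoderm 8 of 7063 genes had higher and 8 lower effects, with Igfbp5 (6.59 ± 1.58), the imprinted Plagl1 (5.55 ± 1.12) and Nnat (4.50 ± 1.05), Col1a2 (4.04 ± 0.85) and Vegfc (2.17 ± 0.46) higher and Ppp2r5a (−1.35 ± 0.25) and Alpl (−1.35 ± 0.32) lower. With at least 50 cells per sum (33 sums) 12 genes were called, 5 of them among these 16, and with no filter 11, 10 of them among these. Of 25 imprinted genes 2 had higher effects and none lower (6 and 0 adjusted over the list alone; camera adjusted p = 0.000595, and adjusted p = 0.434 with an estimated correlation).

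In cells sorted from E8.5 chimeras, DNA methylation was higher in TKO than in control cells. Over all covered CpG positions of mm9, 85.2% and 83.5% of calls were methylated in TKO libraries 1 and 2 and 81.4% and 78.8% in control libraries 1 and 2 (69035352, 62798396, 30289720 and 104286558 calls). Each library was read over its own covered positions. Over the 8490195 positions covered in every library, TKO libraries 1 and 2 stood at 85.8% and 84.5% and control libraries 1 and 2 at 81.5% and 79.5%. In windows with over 50 CpG positions the levels were 10.6% and 8.41% against 5.78% and 4.53%, with 21 to 50 positions 76.4% and 74.9% against 68.1% and 63.9%, and with 1 to 2 positions 86.6% in both TKO against 86.5% and 86.1%. With 2 libraries per group the exact permutation test cannot go below p = 0.33, which the overall level gave.

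**Figure D5:**
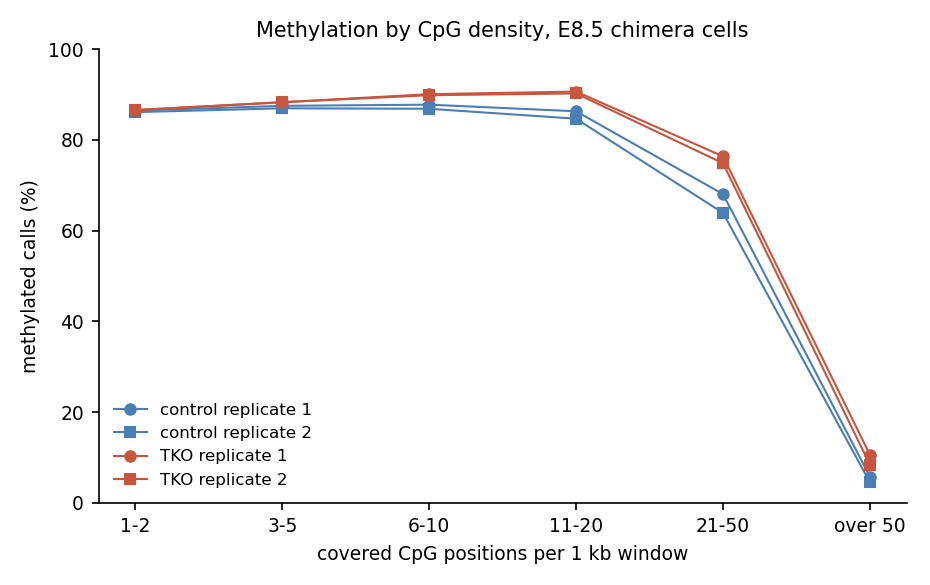
Percent of methylated calls in windows of 1000 bp by the number of CpG positions per window, for 2 TKO and 2 control libraries. In windows with over 50 positions TKO libraries stood at 10.6% and 8.41% and control libraries at 5.78% and 4.53%.

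Of 609045 windows tested, 45159 gained and 1090 lost methylation in TKO cells, 97.6% of calls being gains, and 115366 had an unadjusted p under 0.05. The largest gains with at least 30 calls in each library were on chromosome 16 from 90298001 to 90299000 (4.38% to 96.5%, 71 to 169 calls per library), chromosome 5 from 120293001 (5.00% to 91.3%), chromosome 11 from 57651001 (3.82% to 85.5%), chromosome 1 from 156731001 (8.43% to 89.7%) and chromosome 4 from 134711001 (8.04% to 89.1%). The largest losses were on chromosome 2 from 131654001 (81.1% to 30.7%), chromosome 3 from 116824001 (91.0% to 43.2%), chromosome 1 from 181929001 (95.8% to 49.4%) and from 185839001 (84.8% to 40.2%), and chromosome 7 from 7252001 (47.3% to 2.07%), in mm9. Genes at these windows were not analysed here. Without control library 2, the deepest, 5640 windows were called, and without TKO library 1 or 2 28223 or 29982.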

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

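The tests of Hspa8 and its 3 companions, of Tet1 and of injected cells in extraembryonic mesoderm, and of stage and clones for blood were chosen only after the results were seen; for the other epiblast genes, depth, clustering and other splits, what each explanation predicts was written before that test's result was seen. The clone and double-knockout comparisons and the new clusters that some of these use were themselves added after the main results were seen. Hspa8, Rpl34;Rpl34-ps1, Tpm3 and Mid1 were far lower in TKO than in control whole embryos, and their effects differed from those in chimeras (Hspa8 −3.69, Mid1 −3.40, Rpl34;Rpl34-ps1 −3.08, Tpm3 −2.58), though with cluster 0 cells alone Tpm3 was not called there. The tables argue against loss of the Tet genes, since the median of the 4 in TKO23 against injected control epiblast was −0.12, and against library date, since on shared dates the value nearest 0 was −4.11. A difference between stem cell lines is a candidate explanation: the lowest of the 4 in TKO23 was −0.41, and the highest in TKO26 and TKO29 −3.90. For the other genes called there 83.7% had the same sign in TKO23, but control stem cells were the reference of both comparisons, so a line difference and loss of Tet cannot be told apart.

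Acta2, Tagln, Plac8 and Col1a1 were lower in extraembryonic mesoderm of TKO, DKO12 and DKO13 but not of DKO23 cells, and Asb4 was lower in all 4. The tables argue against injection itself, with a median of 0.30 over the 5 genes in injected control against host cells, and against depth, since knockout sums held at least 0.909 of the depth of host sums. Whether loss of Tet1, which DKO23 cells keep, has a part cannot be told. The test of DKO12 and DKO13 against DKO23 ran on genes picked for this pattern, so it decides nothing, and each double knockout came as its own line. In whole TKO embryos, which lack Tet1, Plac8 (−2.64 ± 0.26) and Asb4 (−1.04 ± 0.37) were lower and Acta2, Tagln and Col1a1 were not called.

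Haematoendothelial cells were fewer among TKO than control cells in chimeras and not in whole embryos, a difference of 5.61 points. Control shares were unlike, at 5.70% in chimeras and 2.78% in whole embryos. Clustering is argued against by an adjusted p of 0.00016 with clusters made without the called genes. The clones are argued against by a lower share than control cells in TKO26 and TKO29 taken singly, the larger unadjusted p being 0.0156. After adjustment TKO26 alone lost the call against control cells, and each clone alone lost it against host cells. A clone alone has fewer embryos than all clones together, so a lost call need not mean a smaller difference. A later stage of the TKO whole embryos may hide a lower share there and cannot be told apart: on shared dates the share was lower, with an adjusted p of 0.0670.

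In extraembryonic mesoderm the TKO effect was higher in whole embryos than in chimeras for Igfbp5 (6.59), Plagl1 (5.55), Nnat (4.50), Col1a2 (4.04), Dcaf12l1 (2.43) and Vegfc (2.17). It was lower for Hspa8 (−3.69), Rpl34;Rpl34-ps1 (−3.28), Alpl (−1.35), Ppp2r5a (−1.35), Gas5 (−1.24) and Rpl41 (−1.08), and in epiblast it was higher for 2310039H08Rik (1.46), which was not called with cluster 0 cells alone. Tests between double knockouts in extraembryonic mesoderm gave Nnat 3.04 for DKO12 against DKO13. For DKO12 against DKO23 they gave Acta2 −2.11, Col1a1 −2.34, Plac8 −1.84 and Tagln −2.54, and for DKO13 against DKO23 Col1a1 −2.39, Nnat −3.46, Plac8 −2.43 and Tagln −2.35. Wells with a cell and no clear genotype numbered 6203 and were not analysed, and neither were 18537 wells without annotation that are not listed as empty, 3213 of them with about as many UMIs as kept cells.

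Single embryos lay far from the rest of their group (CPM) in 49 of 473 groups of 4 to 10 embryos tested (10.4%), where chance gives about 1 in 20. In whole-embryo control cells these were Tet1 (124) and Foxc2 (181) in nascent mesoderm, and Hba-x (21.9) and Hbb-bh1 (56.2) in extraembryonic mesoderm. In chimeras with TKO cells they were, in epiblast, Grb10 (631), Crip2 (120.0), Dnmt3b (4177) and Apoe (292) in host cells and Nnat (58.8) and Gm7324;Rbmx (67.2) in TKO cells, and in caudal epiblast AK207688 (27.8) in host cells. In extraembryonic mesoderm they were Acta2 (600.4), Tagln (143), Hspa8 (679) in TKO cells and Asb4 (957), Nnat (545) and Fmr1nb (145) in host cells, of which Acta2, Tagln, Asb4 and Nnat came from embryo TKO29_16.

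Against control cells they were Tet1 (26.3), Mixl1 (245) and Hand1 (929) in control caudal epiblast of embryo TKO26_1, Sox3 (146) in TKO caudal epiblast, and in extraembryonic mesoderm Tet3 (43.7) and Tagln (374) in TKO and Ccng1 (398) in control cells. For control against host cells they were Igf2 (8888), Pfn1 (811) in extraembryonic mesoderm and Hspa8 (2145) and Pfn1 (687) in rostral mesoderm. In DKO12 caudal epiblast they were Bmp4 (357) and Hand1 (1523) of embryo DKO12_7, with Msx1 (481), Phlda2 (2091), Hand1 (798) and Fn1 (998.7) in host cells of DKO12_3, and Plac8 (208) in extraembryonic mesoderm. Others were Acta2 (1073) in DKO13 cells, Tagln (264) in DKO13 hosts and Tpm3 (345) in DKO23 hosts.

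With AAV-Cre they were Usp9x (251) in epiblast, and in nascent mesoderm Krt18 (137), Ccng1 (90.01) and H19 (589), with Tet1 (125), Krt18 (58.2) and Spry2 (269) in control cells. In primitive streak they were Nodal (282), with T (1189), Car2 (475) and Peg3 (235) in control cells.

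Other splits of the same embryos were fitted for 46 results, with a threshold set per result and not adjusted over the 46. In 28 of them a share under 0.05 of the splits called as many genes, which by itself does not exclude chance for any single result. In whole embryos 1 of 100 splits did, the real one, for epiblast (2174 genes, highest other 7), nascent mesoderm (1063, 74), extraembryonic mesoderm (1722, 4), caudal epiblast (374, 149), endoderm (158, 23), erythroid cells (272, 118) and streak (516, 3). With AAV-Cre it was 1 of 56 for caudal epiblast (780, 10) and 1 of 100 for endoderm (980, 155), epiblast (2935, 3), extraembryonic mesoderm (1608, 90), streak (1227, 140) and nascent mesoderm (2484, with the highest other split calling 9.18% as many). For TKO against host cells it was 1 of 100 for caudal epiblast (378, 18) and 1 of 64 for epiblast (477, 262) and extraembryonic mesoderm (222, 131). For TKO against control cells it was 1 of 32 for caudal epiblast (255, 52) and 1 of 64 for extraembryonic mesoderm (321, 159), and for DKO12 extraembryonic mesoderm 1 of 100 (109, 79).

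For the difference between whole embryos and chimeras 3 of 100 splits called as many in epiblast, where the real count was 5 and another split called 60. What the split with 60 calls separated was not examined. In extraembryonic mesoderm 1 of 100 splits called as many (16, 2). For TKO23 against control cells it was 1 of 100 in epiblast (835, 65), nascent (438, 36) and extraembryonic mesoderm (433, 2), and for TKO26 and TKO29 1 of 100 in these types (1475, 1; 749, 203; 560, 183). The DKO13 effect against that of DKO23 was reached by 1 of 35 splits (7, 2). That of DKO12 against DKO23 was reached by 3 of 50 (25, 88) and that of DKO12 against DKO13 by 9 of 50 (1, 41), so chance is not excluded for their counts. What the highest of these splits separated was not examined.

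The splits were too few for a share under 0.05 in 16 results. With 1 split as large in each, these were TKO against host forebrain (201, highest other 0), nascent (10, 1) and paraxial mesoderm (65, 0), TKO against control epiblast (129, 0), and control against host caudal epiblast (22, 0), extraembryonic (16, 1) and rostral mesoderm (16, 1). They were also DKO12 caudal epiblast (203, 30), forebrain (3, 2), lateral (79, 0) and paraxial mesoderm (64, 0), DKO13 extraembryonic mesoderm (51, 1), and DKO23 caudal epiblast (41, 0), extraembryonic mesoderm (73, 2), forebrain (52, 2) and paraxial mesoderm (20, 1).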

How the results depend on the processing

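The tests with date as a term or of shares on shared dates, with cluster 0 cells, of shares by clone, of clones against injected control cells without pairing, and with clusters made without the called genes were chosen after seeing the results. The others were set before the data were examined. Of 2188 values of the single genes followed under alternatives, 1869 kept their direction and call, 318 lost the call and 1 reversed: T in the epiblast of whole embryos, at 0.99 with cluster 0 cells only. Of 67 called gene lists, 56 lost the call with an estimated correlation in camera and 11 did not, and of 279 counts of called genes over all cell types, 120 changed by more than a factor of 1.5.

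In whole embryos on shared dates, 1104 genes were called in epiblast and 423 in nascent mesoderm, and 1088 and 263 with date as a term. With DESeq2, TKO against host cells gave 124 genes in caudal epiblast, 143 in epiblast and 97 in extraembryonic mesoderm, and TKO against injected control cells 73, 22 and 136. It gave 5 in each type for control against host cells, 56 and 45 in caudal epiblast and extraembryonic mesoderm for DKO12, 17 for DKO13, and 11 and 7 in extraembryonic mesoderm and forebrain for DKO23. For the difference between whole embryos and chimeras it gave 3 in epiblast and 26 in extraembryonic mesoderm. With no filter, extraembryonic mesoderm gave 352 for TKO against host, 490 against control, 47 for control against host, 266 for DKO12 and 102 for DKO13, rostral mesoderm 25 for control against host and DKO12 caudal epiblast 308. With at least 50 cells, DKO12 extraembryonic mesoderm gave 2 and the difference in epiblast 10.

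Without the embryo block, so with host and injected cells not paired, TKO against host cells gave 71 in caudal epiblast, 238 in epiblast and 12 in extraembryonic mesoderm, and TKO against control cells 49, 33 and 61. Control against host cells gave 1 in each type, DKO12 62 and 41, DKO13 9, and DKO23 13 and 5. Methylation windows with clone number as a replicate block numbered 47057.

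Clones moved counts as well. Against host cells, leaving out TKO26 gave 91 genes in caudal epiblast and 39 in extraembryonic mesoderm, and leaving out TKO29 gave 198 in epiblast and 138 in extraembryonic mesoderm. Against control cells of other embryos, TKO23 called 835 in epiblast. Against the same control cells, some of which came from the same embryos and were not paired, TKO26 with TKO29 called 1475 there and 560 in extraembryonic mesoderm. Leaving out embryos one at a time gave 13 to 209 genes in TKO against control epiblast, 5 to 25 in control against host extraembryonic mesoderm, 82 to 204 in DKO12 caudal epiblast, 27 to 68 in DKO13 extraembryonic mesoderm and 26 to 37 in DKO23 forebrain.

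Differences in share are in points. On shared dates, where they are averaged within date and so differ from those of the plain means, whole embryos gained a call in endoderm (−3.81) and epiblast (38.35) and lost it in forebrain (−1.95), lateral mesoderm (−1.59), node (−0.605), paraxial mesoderm (−4.11) and rostral mesoderm (−1.345). With clone TKO26 alone, forebrain (−1.36), node (−0.783) and rostral mesoderm (−1.72) lost it, and with TKO29 alone forebrain (−1.40) and lateral mesoderm (−1.56) lost it and caudal epiblast (−3.29) gained it. With clusters made without the called genes, caudal epiblast (−1.80) and nascent mesoderm (−7.77) gained it.

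For TKO against host cells, clone TKO23 alone (5 embryos, which cannot reach the threshold after adjustment) gave cardiac mesoderm 0 (no such cells on either side, so the fall seen over all clones was absent), caudal epiblast 7.17, endoderm −15.2, erythroid −14.5, extraembryonic mesoderm 16.6, forebrain −0.374, haematoendothelial −2.52, node −1.25 and streak 3.80. Clone TKO26 lost the call in cardiac mesoderm (−0.20), caudal epiblast (4.83), forebrain (−4.65), haematoendothelial cells (−2.26), node (−0.705) and streak (4.02). Clone TKO29 lost it in cardiac mesoderm (−1.36), extraembryonic mesoderm (6.99), forebrain (−2.27), haematoendothelial cells (−1.96), node (−0.606) and streak (3.42). With fewer embryos per clone than over all clones, a lost call need not mean a smaller difference. New clusters ended the call in cardiac mesoderm (−0.758) and made one in nascent mesoderm (4.39), and at least 50 cells ended that of streak (2.66).

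For TKO against control cells, TKO26 alone lost the call in caudal epiblast (10.3), endoderm (−4.58), erythroid (−5.05), forebrain (−2.98), haematoendothelial (−4.11), node (−1.08), paraxial (1.97) and streak cells (10.7). TKO29 alone lost it in caudal epiblast (6.67), erythroid (−0.778), forebrain (−3.93), node (−0.418), paraxial (1.04) and streak cells (5.03). Here too a clone alone has fewer embryos, so a lost call need not mean a smaller difference. At least 50 cells ended it in erythroid (−2.23), node (−0.587), paraxial (1.84) and streak cells (1.68), and new clusters in caudal epiblast (1.59) and paraxial mesoderm (0.649).

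In DKO12, new clusters ended the call in epiblast (1.45) and paraxial mesoderm (3.05) and made one in nascent mesoderm (3.71), and at least 50 cells made one in forebrain (−3.44). In DKO13, new clusters made a call in caudal epiblast (7.003), and at least 50 cells ended it in endoderm (−10.7), erythroid (−9.79), haematoendothelial (−3.75), paraxial (6.70) and rostral cells (2.81). Windows of methylation numbered 29143 at a difference of 20 points, 13979 with limma, and 5640 to 44147 leaving out 1 library. Embryos of all ages and a minimum of 2000 UMIs were not run as alternatives, since the files give no age per embryo and the lowest kept cell held 2041 UMIs.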

Other observations

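The tests by clone were chosen after seeing the results. H19, averaged over all embryonic cells, differed between groups: 24.0 CPM in control whole embryos, 95.3 in injected control cells, 195, 176 and 135 in DKO12, DKO13 and DKO23 cells, 684 in AAV-Cre embryos and 2060 in host cells of TKO chimeras. Injected TKO cells of clones TKO26 and TKO29 stood at 1306 and 1174 and those of TKO23 at 128, so it did not sort by stem cell against embryo origin. Ccng1 was higher in cells of clones TKO26 and TKO29 than in injected control cells in epiblast (log2 0.60 ± 0.22, edgeR BH-adjusted p = 0.0350) but not in cells of TKO23 (−0.62 ± 0.24, edgeR BH-adjusted p = 0.0862). Hspa8 varied among host cells of the 27 TKO chimeras measured, from 3.39 to 1979 CPM. Spike-in RNA differed between groups, with a median of 66 UMIs per cell in control and 5 in TKO whole embryos, and of 46 in injected control, 2 in TKO and 11 in host cells of chimeras. TKO and control whole embryos came mostly on separate plates. In chimeras TKO and host cells also came from plates without control cells. These medians therefore compare plates as well as genotypes.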
